A study of Homo sapiens with 6 samples.

How the data were processed

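Poly(A) RNA was sequenced from HCT116 cells, a human colorectal carcinoma line, that carried either a control short hairpin RNA (shControl) or a hairpin against FBL (shFBL). All cells were kept overnight in 5 µM mitomycin C, a drug that crosslinks the strands of DNA. Each group had 3 libraries. Per the labels' protocols, poly(A) RNA was picked with oligo(dT) beads in repeated rounds, a strand-marking dUTP kit was used, and paired reads were taken on a NovaSeq instrument. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

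The deposited table gives the authors' FPKM (fragments per kilobase of transcript, scaled to the total of the library) for 34485 genes in each library, per the file headers. Beside these it gives the authors' fold change as a ratio of group means, its log2 value, a p-value and a q-value for each gene, per the file headers. For all 27155 genes with both means above 0 the deposited log2 fold change equalled the log2 ratio of the mean FPKM to within 0.01 (100% of them). A second deposited table holds the authors' enrichment score, its normalised score, a nominal p-value and a false discovery rate q-value for 304 KEGG gene sets. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9. The gene identifiers of the table are human, so these notes cannot describe how the FPKM values were made. The human build, the annotation, the program behind the FPKM values and the authors' test are not given in the sources used here. No coordinates are printed for that reason, and whether strand was used in assigning reads is not known.

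FPKM values are relative to all fragments counted in a library, so RNAs that take a larger share lower the values of the rest. They are not counts, and the low values of genes with 1 transcript of over 500 bases stepped in units whose commonest sizes stood in a ratio of about 2, so whole reads were not recovered and absolute depth is unknown. The size of these steps gave relative depth. Against the deepest library, shControl replicate 1, depth was 96% and 92.7% in shControl replicates 2 and 3. It was 83.3%, 90.3% and 85.7% in shFBL replicates 1, 2 and 3. The precision of single values therefore rests on the spread between 3 libraries.

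Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested (13076 genes). Values were transformed as log2(FPKM + 1), and fold changes are shFBL minus shControl on this scale, which understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend in the empirical Bayes step, no block, and Benjamini-Hochberg adjustment at 0.05. FBL and YBX1 were also compared by an exact two-sided permutation test over the 20 assignments of the libraries, which cannot go below p = 0.1. Gene lists, tests and the rule for named genes were chosen before the data were examined. The table was expected to hold either counts or FPKM, and the test written down for FPKM was used. Of 1376 genes on 49 lists, 1345 were matched to the table by symbol, and 45 lists had at least 3 tested genes. Lists were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01 and adjustment over the 45 lists. Camera with an estimated correlation and fry, which tests a list on its own, were run beside it. Intervals on list medians are 95% bootstrap intervals over genes from 10000 draws, which treat genes as independent.

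The genes named are FBL and YBX1, the 10 largest rises and the 10 largest falls, and up to 4 members of a list. The rises and falls were taken among genes with a gene symbol rather than a clone or RNA family name. They had to pass an adjusted p of 0.05, have non-overlapping groups and reach a mean of 5 FPKM. The list members are those with the smallest adjusted p, for lists past the threshold or with members past it, and for the DNA repair, checkpoint, p53, box C/D and YBX1 lists whether or not they passed. A few genes that this rule takes are not used here. Other genes are said to have been chosen after their values were seen.

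Alternatives set beforehand were median-ratio scaling, quantile normalization, a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, limma without the trend, array weights, a fold change of at least 2, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were a GC and length correction, a restriction to nuclear protein-coding genes, a scaling on nuclear protein-coding genes outside the histone list, and leaving out the shFBL libraries with haemoglobin transcripts. The correction removed from each library a loess trend (span 0.5) on transcript GC content and length from the GENCODE v29 transcripts, medians over each gene's transcripts, which gave values for 99.97% of the tested nuclear protein-coding genes.

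The fit was tested on simulated data for the comparison of shFBL with shControl, with the means and residual spread of the 13076 genes and 200 genes changed. It recovered 65.7% of the genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 97% of those changed by 2. A further 40 genes, each raised by 0.5, formed a planted list. Of 205 calls, those of planted genes included, 4 were false. A planted list was found, and 0 of the unchanged lists were called by camera among the 45 simulated lists. The simulation took over the means and spread of single genes, not the correlation between genes of a real list. That correlation was estimated at 0.5 for the G2/M and mitosis list and 0.523 for cytosolic ribosomal proteins, against the preset 0.01. The simulation therefore cannot show how often camera calls a real list falsely. The changed and planted genes were drawn only from genes at about 5 FPKM or more in shControl. Recovery is therefore not known for lower genes, and it was given by size of change and not by level. A planted GC trend without changed genes gave 1565 calls among 10927 genes before the correction and 0 after it.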

Results

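FBL encodes fibrillarin, the methyltransferase of box C/D small nucleolar ribonucleoproteins, which places 2'-O-methyl groups on ribosomal RNA. The series asks, by its title, how FBL acts on proliferation and DNA damage repair of cancer cells through YBX1, a nucleic acid binding protein. Here the transcriptomes of 3 shControl and 3 shFBL libraries of HCT116 cells were compared, all after 5 µM mitomycin C, so no comparison with undamaged cells was made. FPKM summed to between 281558 and 312636 per library. A value above 0 was listed for 25062, 24433 and 24795 genes in shControl replicates 1, 2 and 3, and for 27254, 27143 and 26937 genes in shFBL replicates 1, 2 and 3, although relative depth was lower in shFBL. Libraries of 1 group differed by a median of 0.102 to 0.157 on the log2 scale, and libraries of different groups by 0.22 to 0.26. No pair of libraries shared more than 5 identical values among the tested genes.

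The FBL transcript (ENSG00000105202) was lower in all 3 shFBL libraries. Its level was 86.8 ± 4.08 FPKM (SD, n = 3) in shControl and 18.1 ± 0.427 FPKM (SD, n = 3) in shFBL. This was 20.9% of the control level, or 4.79-fold lower. On the log2 scale the change was -2.20 with a standard error of 0.065 (limma, adjusted p = 1.43e-07). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. FBL was among the 10 largest falls of the whole comparison. Among the 12 tested proteins of the box C/D particle and its assembly, 2 rose, 1 fell and 9 did not pass the test, with the same counts adjusted over the list alone. The fall was FBL itself. NOP58, a core protein of the same particle, rose from 21.9 ± 0.847 to 27.8 ± 0.709 FPKM (log2 change 0.33, adjusted p = 0.00559), and the assembly factor gene C12orf45 rose by a log2 change of 0.39 (adjusted p = 0.0311). NOP56, the other scaffold protein, stood at 72.3 ± 2.8 FPKM in shControl and 81.0 ± 4.92 FPKM in shFBL and did not pass (adjusted p = 0.0999), though it did after the GC and length correction, at a log2 change of 0.20. The list did not pass as a set (adjusted p = 0.932). Its median was -0.02 and its mean -0.12, while camera ranked it upward.

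YBX1 (ENSG00000065978) did not fall. Its level was 113 ± 1.8 FPKM (SD, n = 3) in shControl and 122 ± 3.05 FPKM (SD, n = 3) in shFBL, a log2 change of 0.12 with a standard error of 0.056 (limma, adjusted p = 0.144). All 3 shFBL values lay above all 3 shControl values, and the exact two-sided permutation test gave its smallest possible p of 0.1. The change passed the threshold under quantile normalization (adjusted p = 0.0107), scaling on nuclear protein-coding genes (0.0104) and the GC and length correction (0.00601). Over all alternatives the adjusted p ran from 0.00601 to 0.578 and the direction stayed upward. Of 9 tested Y-box proteins and partners of YBX1, 0 rose and 2 fell, over all genes and adjusted over the list alone. The fallen members were HNRNPU, a nuclear RNA binding protein, at a log2 change of -0.37 (adjusted p = 0.0131), and the poly(A) binding protein gene PABPC1 at -0.24 (adjusted p = 0.0338). The RNA helicase gene DHX9 had a log2 change of 0.20 (adjusted p = 0.0702) and SYNCRIP one of -0.17 (adjusted p = 0.123). The list did not pass (adjusted p = 0.904).

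**Figure D1:**
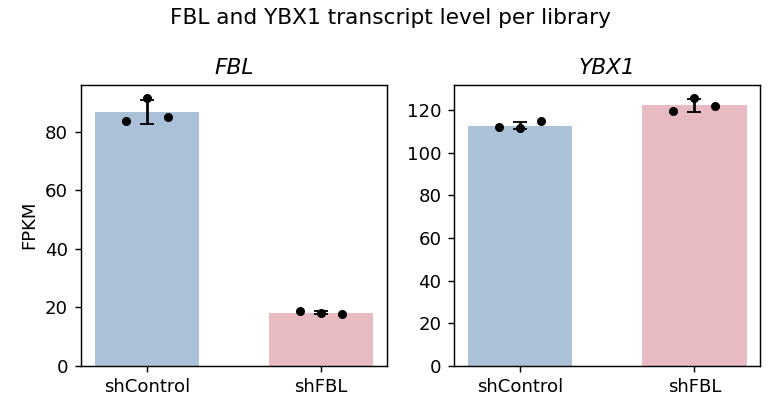
FPKM of FBL and YBX1 in each library, with bars for the mean of 3 libraries, error bars for 1 SD and points for single libraries. FBL fell from a mean of 86.8 to 18.1 FPKM, and YBX1 stood at 113 and 122 FPKM.

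Across the transcriptome the comparison divided by kind of gene. Of 13076 tested genes, 1793 were higher and 2352 lower in shFBL (limma, adjusted p under 0.05). Protein-coding genes leaned downward, with 1266 higher and 2270 lower of 10943. The other 2133 genes, mostly non-coding, leaned upward, with 527 higher and 82 lower. The median log2 change of protein-coding genes was only -0.036. Their share of all FPKM was 86.3% ± 0.75 in shControl and 73.0% ± 1.9 in shFBL, so their downward lean may depend on the FPKM scale. Most changes were small, and 115 rises and 47 falls reached 2-fold. The groups did not overlap for 46.5% of the tested genes, where chance gives 10%. The largest falls after FBL were PPDPF (64.5 ± 4.2 to 21.1 ± 1.32 FPKM, log2 change -1.57), the hair keratin-associated gene KRTAP3-1 (-1.56), PKMYT1, the kinase that holds CDK1 inactive before mitosis (-1.47), the replication licensing factor CDT1 (-1.44), the kisspeptin receptor KISS1R (-1.40), the mitotic kinase AURKB (-1.21), RNASEK (-1.20), the mitochondrial carrier SLC25A10 (-1.19) and the ribonucleotide reductase subunit RRM2 (-1.18). Their adjusted p lay between 2.04e-06 and 0.00163. RNASEK overlaps a read-through gene, RNASEK-C17orf49, which rose by 1.03 (adjusted p = 0.0153, chosen after its values were seen), so the split of reads between the pair is uncertain. The 10 largest rises were all non-coding RNAs, described with the RNAs without poly(A) tails.

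The share of calls that were higher was 43.3% with the values as deposited, and 61.5% (3275 higher, 2048 lower) when the libraries were scaled on nuclear protein-coding genes. The number of higher genes fell to 1172 without shFBL replicate 1 and to 1167 without shFBL replicate 2, and 809 higher and 940 lower genes were called when the 2 shFBL libraries with haemoglobin transcripts were left out.

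Genes of DNA replication and of mitosis fell together. Of 47 tested genes of DNA replication and the G1/S transition, 43 fell and 0 rose (46 and 0 adjusted over the list alone), with a median log2 change of -0.48 (95% bootstrap interval -0.57 to -0.44). CDT1 fell from 60.7 ± 1.93 to 21.8 ± 1.08 FPKM, or 2.79-fold. The thymidine kinase gene TK1 fell from 132 ± 6.73 to 63.1 ± 0.357 FPKM and RRM2 from 74.6 ± 4.54 to 32.4 ± 1.17 FPKM. The flap endonuclease FEN1, which trims Okazaki fragments, fell from 111 ± 6.81 to 60.0 ± 3.0 FPKM. Of 59 tested genes of G2/M and mitosis, 48 fell and 1 rose (51 and 1 adjusted over the list alone), with a median of -0.56 (-0.63 to -0.49). AURKB fell from 40.7 ± 0.616 to 17.1 ± 1.01 FPKM. FOXM1, the transcription factor of the mitotic programme, fell from 35.9 ± 1.75 to 16.8 ± 0.387 FPKM, the cohesion factor CDCA5 by a log2 change of -0.87 and the ubiquitin-conjugating enzyme UBE2C by -0.78. Camera with the preset correlation gave adjusted p = 1.47e-18 for the replication list and 1.21e-18 for the mitosis list. Both calls were lost with an estimated correlation, where each list had an adjusted p = 0.756. After the GC and length correction the medians were -0.49 and -0.58.

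Replication-dependent histone genes moved the other way. These genes serve S phase and their transcripts largely end in a stem-loop without a poly(A) tail. Whether the histone transcripts counted here had a tail was not measured. Of 19 tested, 18 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 change of 1.46 (1.05 to 1.82). The other 26 of the 45 genes lay below the filter, which a gene can pass through its rise, so these counts and the median favour genes that rose. Without the filter the mean FPKM was higher in shFBL for 45 of 45 genes, and their summed FPKM was 29.7 ± 2.23 in shControl and 180 ± 15.1 in shFBL. H1-2 rose from 4.20 ± 1.23 to 32.7 ± 0.531 FPKM, H2BC5 from 3.99 ± 0.565 to 27.2 ± 4.03 FPKM, H2BC12 by a log2 change of 2.35 and H2AC18 from 3.87 ± 0.204 to 23.0 ± 2.88 FPKM. H2AC18 has a near-identical copy, H2AC19 (chosen after its values were seen), with a log2 change of 2.29 in both, so reads may be shared between the copies. The list passed with the preset correlation (adjusted p = 1.3e-15) and not with an estimated one (adjusted p = 0.285). Among 8 histone genes with polyadenylated transcripts, chosen after their values were seen, 0 rose and 7 fell. The linker histone gene H1-10 fell from 116 ± 3.14 to 65.4 ± 4.32 FPKM and H2AZ1 from 186 ± 4.63 to 145 ± 6.02 FPKM.

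Many RNAs outside the histone list that lack poly(A) tails rose as well. The 10 largest rises were RN7SL2, RN7SL1, RN7SL3 and the pseudogene RN7SL4P of the signal recognition particle RNA, RN7SK, RMRP, RPPH1, MALAT1 and the 5.8S ribosomal RNA genes RNA5-8SN3 and RNA5-8SN2. RN7SL2 rose from 2.70 ± 1.5 to 342 ± 128 FPKM (log2 change 6.52). RN7SK, the RNA that holds the elongation factor P-TEFb inactive, rose from 2.87 ± 1.01 to 110 ± 9.32 FPKM (log2 change 4.88). RMRP, the RNA of RNase MRP, rose from 1.20 ± 0.494 to 60.9 ± 10.8 FPKM. RPPH1, the RNA of RNase P, rose from 0.948 ± 0.705 to 42.5 ± 10.4 FPKM. MALAT1, a nuclear long non-coding RNA whose 3' end is a triple helix, rose from 8.37 ± 0.618 to 111 ± 2.45 FPKM, or 13.2-fold (adjusted p = 9.48e-09). The copies of the 7SL and 5.8S genes are near-identical, so values of single copies are uncertain. Box C/D snoRNAs, the class that FBL binds, had 11 rises and 0 falls among 36 genes with a median of 0.55 (0.32 to 0.85). Box H/ACA snoRNAs, which FBL does not bind, had 5 rises and 0 falls among 20 with a median of 0.59 (0.43 to 0.83). The filter favours genes that rose here too. Over all 149 box C/D snoRNAs of the table the summed FPKM was 138 ± 16.1 in shControl and 201 ± 20.4 in shFBL, and over all 139 box H/ACA snoRNAs 51.0 ± 4.48 and 101 ± 7.37. In log2 of the box C/D sum the lowest shFBL library lay 0.22 above the highest shControl one, less than the range of up to 0.335 within a group. For box H/ACA this gap was 0.791 and the range up to 0.254. All 4 tested U1 genes rose, with a median of 1.89. Of 22 mitochondrial tRNAs 12 rose and 0 fell, with a median of 0.35 (0.08 to 0.76). Their share of all FPKM was 3.55% ± 0.45 in shControl and 3.71% ± 0.2 in shFBL. RNA classes other than the histone list were set up after their values were seen.

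Ribosomal RNA signal took a larger share in shFBL. The 4 clone-named loci FP236383 and FP671120, chosen like the mitochondrial ribosomal RNAs after their values were seen, which lie inside 18S ribosomal RNA units and are annotated on the minus strand, took 1.07% ± 0.063 of all FPKM in shControl and 10.7% ± 2.0 in shFBL (SD, n = 3). The locus ENSG00000281181 rose from 886 ± 48.8 to 9475 ± 1730 FPKM. Without a statement on strand, reads of 18S RNA and of a transcript on the opposite strand cannot be told apart there. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 rose by log2 changes of 1.26 and 0.83, while 10 of 13 mitochondrial mRNAs fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.38. MT-ND1 fell from 3501 ± 78.8 to 1958 ± 82.6 FPKM and MT-CO2 from 13270 ± 226 to 8746 ± 151 FPKM. Mitochondrial mRNAs took 24.6% of all FPKM in shControl and 18.4% in shFBL. Their list passed (adjusted p = 1.22e-05), and did not with an estimated correlation (adjusted p = 0.756).

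**Figure D2:**
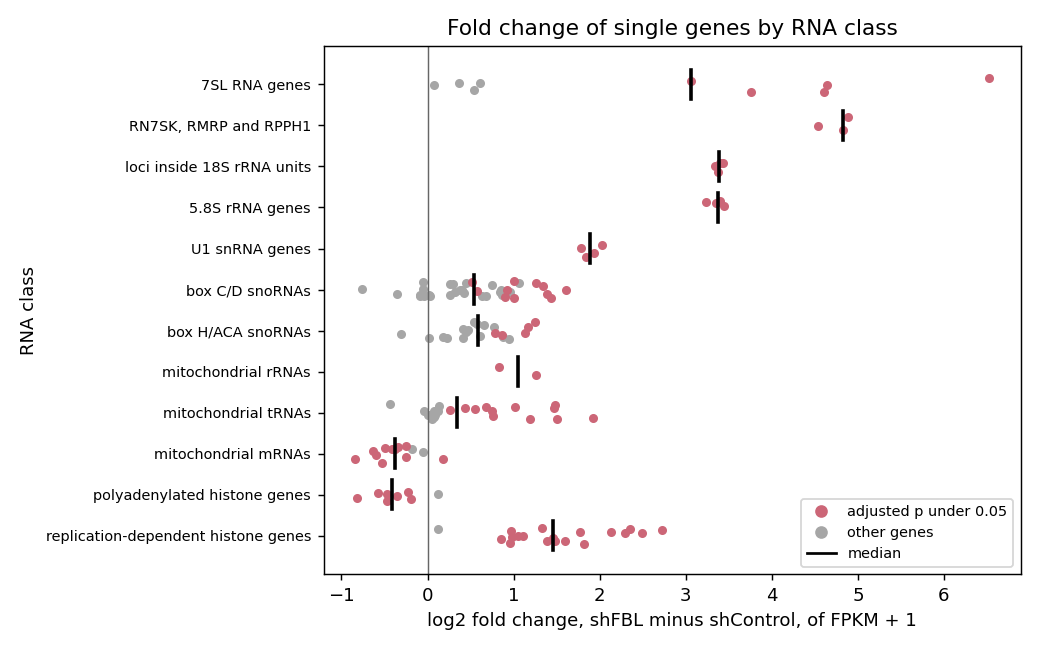
Log2 fold change (shFBL minus shControl, of FPKM + 1) of single genes, one row per RNA class, with red points for genes past an adjusted p of 0.05, grey points for other genes and a black bar for the class median. Medians of the classes without poly(A) tails and of replication-dependent histone genes lie to the right, with single genes up to 6.52 for RN7SL2. Single box C/D snoRNAs and mitochondrial tRNAs reach down to -0.76 and -0.43. Polyadenylated histone genes and mitochondrial mRNAs lie to the left.

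Among the genes of the ribosome and its assembly that passed the test, most were higher in shFBL, by small amounts, and most members did not pass. Of 79 cytosolic ribosomal protein genes, 30 rose and 4 fell (32 and 4 adjusted over the list alone), with a median of 0.16 (0.11 to 0.23). RPL24 rose from 158 ± 11.2 to 212 ± 1.12 FPKM, RPL7 from 303 ± 9.92 to 406 ± 24.9 FPKM, RPS27A by a log2 change of 0.45 and RPL34 by 0.55. Of 72 ribosome biogenesis genes, 22 rose and 3 fell (23 and 3 adjusted over the list alone), with a median of 0.16 (0.11 to 0.20). The strongest of these encode parts of the small subunit processome, which folds the 18S precursor. UTP20 rose by 0.90, UTP6 by 0.59, WDR75 by 0.57 and UTP18 by 0.52 on the log2 scale. Of 16 snoRNA host genes, 11 rose and 1 fell, over all genes and adjusted over the list alone, among them SNHG8 (2.97 ± 0.201 to 5.89 ± 0.186 FPKM), SNHG5, SNHG17 and TAF1D. The lists passed with adjusted p = 2.52e-06, 2.63e-05 and 8.38e-05, and did not with an estimated correlation (adjusted p = 0.992, 0.992 and 0.756). By fry the ribosomal protein (adjusted p = 0.0975) and ribosome biogenesis (0.112) lists did not pass. The library medians of the ribosomal protein list were -0.08, 0.02 and 0.05 in shControl and 0.11, 0.24 and 0.15 in shFBL, a gap of 0.058 between groups against a range of up to 0.132 within a group. In another split of the 6 libraries into 3 and 3 that list reached an adjusted p of 9.5e-18.

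Among the other lists on translation, RNA polymerase I had 4 rises, led by TAF1D (log2 change 0.53) and RRN3 (0.40), and 1 fall, UBTF (-0.25), of 15 genes (adjusted p = 0.122). After the GC and length correction UBTF no longer passed, at a log2 change of -0.12. Of 77 mitochondrial ribosomal protein genes 11 rose and 6 fell (9 and 6 adjusted over the list alone, adjusted p = 0.14 for the list). That list passed without shFBL replicate 1 (0.0417), after the GC and length correction (0.0388) and with the scaling on nuclear protein-coding genes (0.0262), and ran up to 0.937 over its alternatives with the preset correlation. Of 42 translation factors 8 rose and 8 fell (9 and 9 adjusted over the list alone, adjusted p = 0.907). The elongation factor EEF2 fell from 490 ± 25.3 to 358 ± 22.7 FPKM, EIF1 fell by -0.40 and EIF3E rose by 0.44 on the log2 scale. The 20 cytosolic tRNA synthetases had 4 rises and 5 falls (adjusted p = 0.907), and the 6 box H/ACA particle proteins had 1 rise, NOP10 at 0.23 (adjusted p = 0.932).

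Mitomycin C crosslinks are repaired by the Fanconi anaemia pathway, and of its 31 tested genes 15 fell and 2 rose (16 and 3 adjusted over the list alone), with a median of -0.24 (-0.37 to 0.04). The ubiquitin-conjugating enzyme UBE2T, which acts on FANCD2, fell from 39.8 ± 1.5 to 28.2 ± 0.307 FPKM. FANCG fell from 25.0 ± 2.26 to 15.6 ± 1.92 FPKM, FANCE by a log2 change of -0.64 and the nuclease gene DCLRE1B by -0.53. The list passed narrowly (adjusted p = 0.0421), and did not with an estimated correlation (adjusted p = 0.992), without shFBL replicate 3 (0.0599), with median-ratio scaling (0.0534) among nuclear protein-coding genes alone (0.115) or without the shFBL libraries that held haemoglobin transcripts (0.112). Over its alternatives with the preset correlation the adjusted p ran from 2.89e-05 to 0.115. Of 36 homologous recombination genes, 11 fell and 4 rose (11 and 5 adjusted over the list alone). RAD54L fell from 9.53 ± 1.25 to 4.08 ± 0.889 FPKM, EXO1 from 18.2 ± 1.17 to 9.99 ± 1.06 FPKM and BABAM1 by -0.47 on the log2 scale, while the kinase gene ATM rose from 1.74 ± 0.196 to 3.81 ± 0.481 FPKM. BRCA1, chosen after its values were seen, fell from 9.40 ± 0.683 to 6.90 ± 0.468 FPKM (adjusted p = 0.00807). The recombination list did not pass (adjusted p = 0.282). It did after the GC and length correction (0.0316) and without a filter on low values (0.00723), and over its alternatives with the preset correlation the adjusted p ran up to 0.558.

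In base excision repair 7 of 20 genes fell and 1 rose (8 and 1 adjusted over the list alone), with FEN1, XRCC1 (-0.58), PARP2 (-0.44) and APEX2 (-0.33) the leading falls. The lists share members, as FEN1 is also on the replication list and EXO1 on both the recombination and mismatch repair lists. Whether the falls of repair genes are separate from that of replication genes was not tested. That list did not pass (adjusted p = 0.132), did without a filter on low values (0.00214), and ran up to 0.68 over its alternatives with the preset correlation. In nucleotide excision repair 5 of 25 fell and 3 rose (5 and 7 adjusted over the list alone, adjusted p = 0.867). The damage sensor DDB2 fell from 26.4 ± 1.33 to 17.9 ± 0.377 FPKM, LIG1 by -0.75 and GTF2H4 by -0.51 on the log2 scale. The median of the nucleotide excision list was nevertheless 0.12 (-0.17 to 0.21) and its mean 0.02, and camera ranked it upward. In mismatch repair 3 of 9 fell and 2 rose, over all genes and adjusted over the list alone (adjusted p = 0.907), with EXO1 and the sliding clamp PCNA (324 ± 13.3 to 239 ± 12 FPKM) among the falls and MSH3 higher (0.57). That list had a median of 0.15 and a mean of -0.03. In end joining 2 of 15 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.867). LIG4 rose by 0.56 and SHLD3 by 0.44, PAXX fell by -0.31, and DCLRE1C had a log2 change of 0.33 that did not pass (adjusted p = 0.0537). After the GC and length correction PAXX and SHLD3 no longer passed, at log2 changes of -0.03 and 0.26, and DCLRE1C did, at 0.28.

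Among 22 checkpoint genes, 9 fell and 2 rose, over all genes and adjusted over the list alone. H2AX, whose product is phosphorylated at broken DNA, fell from 81.6 ± 7.67 to 38.4 ± 2.82 FPKM, TIMELESS from 38.2 ± 3.14 to 19.9 ± 1.38 FPKM and the phosphatase gene CDC25B by a log2 change of -0.78, while ATM rose by 0.81. The list stood just outside the threshold (adjusted p = 0.0542) and ran from 0.000409 to 0.147 over its alternatives with the preset correlation. It passed without a filter on low values (0.000409), after the GC and length correction (0.00856), with the scaling on nuclear protein-coding genes (0.046), and without shControl replicate 1 (0.0466), shControl replicate 2 (0.0378) or shFBL replicate 1 (0.0307). Of 40 p53 targets, 11 fell, 2 rose and 27 did not pass, with the same counts adjusted over the list alone. CDKN1A, the CDK inhibitor p21, fell from 437 ± 23.5 to 255 ± 15.9 FPKM, or 1.71-fold. FDXR fell from 75.0 ± 2.36 to 42.5 ± 3.42 FPKM, TP53I11 by -0.86 and BCL2L1 by -0.67 on the log2 scale. The p53 list did not pass (adjusted p = 0.119) and had a median of -0.05 (-0.18 to 0.07). It passed without a filter on low values (9e-04) and ran up to 0.341 over its alternatives with the preset correlation. With an estimated correlation the recombination, base excision repair, checkpoint and p53 lists each had an adjusted p of 0.992. Apoptosis regulators went both ways, with 3 rises and 5 falls of 32, over all genes and adjusted over the list alone (adjusted p = 0.907). APAF1 rose by 0.73, and BBC3 and BOK fell by log2 changes of -0.58 and -0.60.

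**Figure D3:**
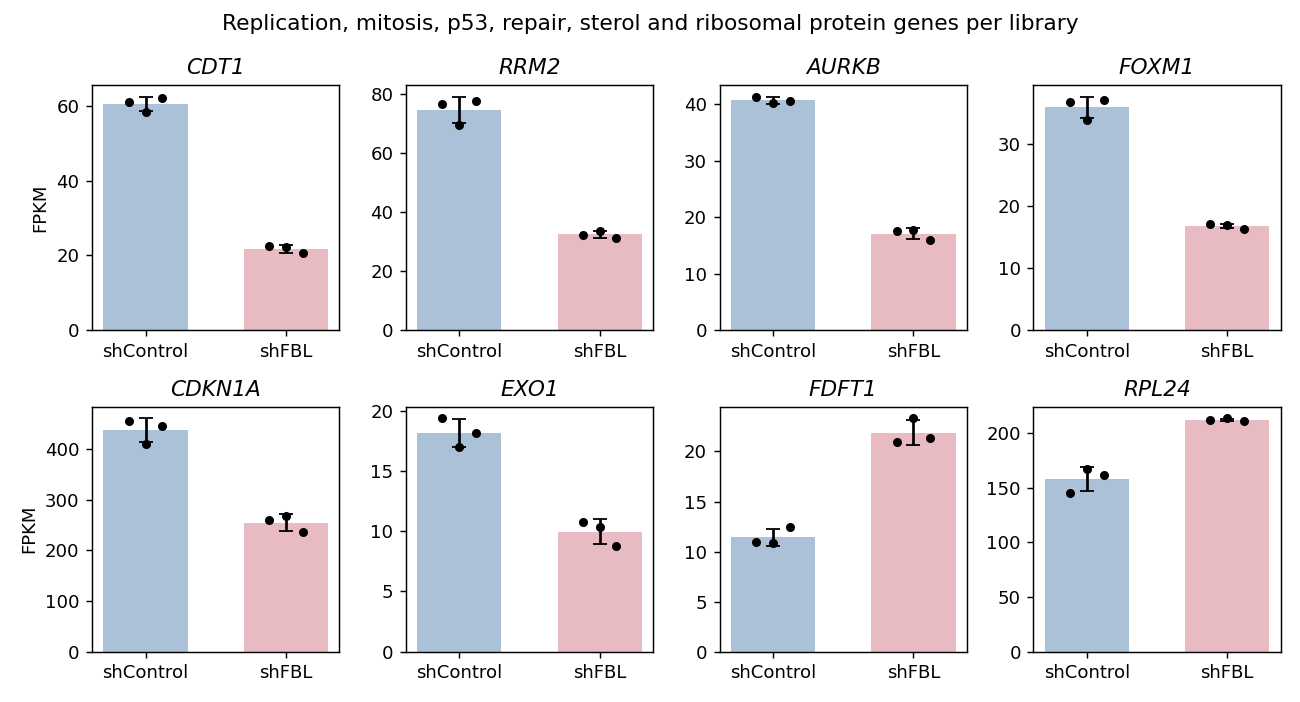
FPKM of 8 named genes in each library, with bars for the mean of 3 libraries, error bars for 1 SD and points for single libraries. CDT1, RRM2, AURKB, FOXM1, CDKN1A and EXO1 were lower in all shFBL libraries and FDFT1 and RPL24 were higher.

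Cholesterol synthesis genes rose. Of 24 tested, 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.46 (0.36 to 0.59). MSMO1 rose from 9.56 ± 0.87 to 21.9 ± 2.79 FPKM, FDFT1 from 11.4 ± 0.859 to 21.9 ± 1.25 FPKM and IDI1 from 14.2 ± 0.782 to 24.7 ± 0.36 FPKM. The list passed (adjusted p = 3.45e-09), and did not with an estimated correlation (adjusted p = 0.756). Nuclear-encoded genes of oxidative phosphorylation showed 16 rises and 8 falls of 76, over all genes and adjusted over the list alone. COX7C rose from 67.0 ± 1.1 to 103 ± 0.771 FPKM and COX6A1 by 0.45, while ATP5MC2 fell by -0.76 and COX8A by -0.59 on the log2 scale. That list passed narrowly (adjusted p = 0.043), and did not with an estimated correlation (adjusted p = 0.992) or without shControl replicate 1 (0.328), shFBL replicate 2 (0.0848) or shFBL replicate 3 (0.123). Median-ratio scaling (0.109), the replicate number as a block (0.0576), no filter on low values (0.207) and the omission of both libraries with haemoglobin transcripts (0.614) also ended its call, and over its alternatives with the preset correlation the adjusted p ran from 0.00495 to 0.614. In another split of the 6 libraries into 3 and 3 this list reached an adjusted p of 2.13e-08.

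Several lists of stress and signalling genes were lower. Of 17 cytoskeleton genes, 12 fell and 1 rose (14 and 1 adjusted over the list alone). ACTB, often used as a reference gene, fell from 294 ± 20.8 to 170 ± 6.93 FPKM, ACTG1 from 859 ± 59.3 to 569 ± 28.3 FPKM, and ACTN4 and ACTN1 by -0.59 and -0.53 on the log2 scale (adjusted p = 9.11e-06 for the list, adjusted p = 0.854 with an estimated correlation). In the integrated stress response 12 of 23 fell and 1 rose (13 and 3 adjusted over the list alone), led by ATF5, PHGDH, SHMT2 and ATF4 (135 ± 7.64 to 94.9 ± 3.07 FPKM). Among 21 immediate early genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), led by NR4A1 (-1.01), JUND, FOSL1 and JUNB. Of 15 Wnt targets 5 fell and 0 rose (6 and 0 adjusted over the list alone), with NOTUM (-0.78), SP5 and NKD2 lower and DKK1 falling from 253 ± 19.2 to 180 ± 13.4 FPKM. Of 13 NF-kB targets 3 fell, TNFAIP2, NFKB2 and RELB, and 0 rose. Of 27 lysosome and autophagy genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), led by CTSD (-0.69). The last 5 of these lists passed with adjusted p = 0.00333, 0.00305, 0.00567, 0.0306 and 0.0421 in this order. With an estimated correlation they had adjusted p = 0.992, 0.992, 0.992, 0.854 and 0.992. After the GC and length correction, run on nuclear protein-coding genes alone, they no longer passed, with adjusted p = 0.0929, 0.411, 0.286, 0.208 and 0.15. Each was the highest over its alternatives with the preset correlation. The lowest were 6.11e-06, 2.54e-07, 0.000194, 0.00297 and 2.89e-05. The lysosome list also did not pass without shControl replicate 3 (0.0534), shFBL replicate 1 (0.0515) or shFBL replicate 3 (0.0693), with the replicate number as a block (0.0507), without the libraries with haemoglobin transcripts (0.0532), among nuclear protein-coding genes alone (0.128) or with the scaling on these genes (0.0682). NKD2 and RELB no longer passed after the correction, at log2 changes of -0.20 and -0.17. In other splits of the 6 libraries into 3 and 3 the lowest adjusted p was 0.00226 for the cytoskeleton list and 0.015, 0.0334, 0.015, 0.0901 and 0.0273 for the other 5 lists, in the order above.

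GC content of the transcripts moved with the group. Across 10927 nuclear protein-coding genes the log2 change had a Spearman correlation of -0.456 with GC content and of -0.017 with length. These are correlations across genes, which are not independent replicates. Among the 2186 genes with the lowest GC content, with a median of 40%, the median change was 0.13, and 634 genes rose and 152 fell. Among the 2186 with the highest, with a median of 62.5%, it was -0.25, and 108 rose and 1078 fell. Single libraries also differed within a group, with correlations of the deviation from the group mean between -0.239 in shControl replicate 3 and 0.116. After the correction 2226 genes were higher and 2302 lower, or 49.2% higher, against 38.3% higher among the same genes before it. The correction also removes the overall shift of each library over these genes, so a more even split is in part built in. The median change over them was -0.036 before and 0.008 after. Of the 16 lists called, 14 could be tested after the correction, of which 9 kept their call and 5 lost it, and 4 other lists gained one. The correction was run on nuclear protein-coding genes alone, so the genes a list is compared with changed as well. Restriction to these genes without the correction gave 11 called lists. Of the 16 lists, 14 also passed in at least 1 other split of the 6 libraries into 3 and 3, all but the NF-kB and Fanconi lists, as did 9 of the 29 lists not called.

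**Figure D4:**
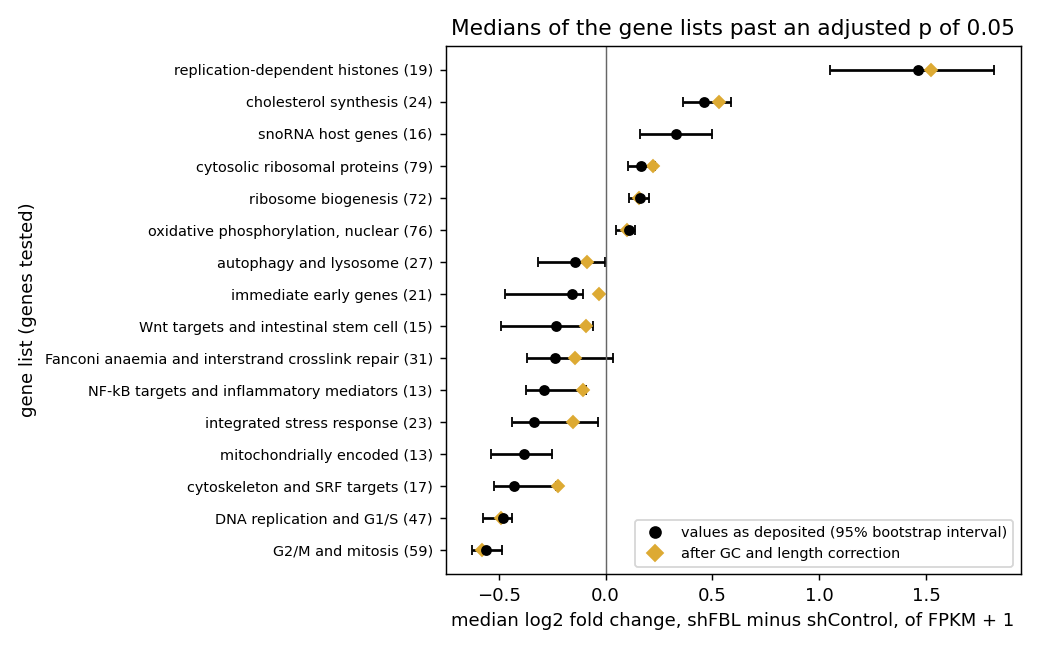
Median log2 fold change (shFBL minus shControl, of FPKM + 1) of the 16 gene lists past an adjusted p of 0.05 with the preset correlation. Black points with 95% bootstrap intervals are the values as deposited and yellow diamonds the medians after the GC and length correction, not drawn for snoRNA host genes and mitochondrially encoded genes. Replication-dependent histones lie highest at 1.46 and the mitosis list lowest at -0.56.

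Markers of other cell types were mostly near 0. No endothelial marker exceeded 0.253 FPKM. Of the fibroblast, kidney packaging line, and mammary and cervical line lists, only COL1A1, PAX2, PAX8 and CDKN2A reached the level for testing, with CDKN2A the highest at 16.6 FPKM in shControl and 13.3 FPKM in shFBL. Blood was the exception. HBB, a haemoglobin gene, stood at 44.9 and 57.2 FPKM in shFBL replicates 2 and 3 and at no more than 0.0387 FPKM in the other 4 libraries. HBA2 stood at 26.3 and 25.8 FPKM in the same 2 libraries against 0.383 to 1.82 FPKM in the others, so its groups overlapped although it passed the test (adjusted p = 0.0352). The neutrophil genes S100A8, S100A9 and DEFA3, chosen after their values were seen, reached 3.15, 4.31 and 3.05 FPKM in shFBL replicate 2 and 1.19, 2.39 and 1.08 FPKM in shFBL replicate 3. The leukocyte marker PTPRC stayed at or below 0.0293 FPKM. The RNAs that rose did so in shFBL replicate 1 as well, where RN7SK stood at 99.8 FPKM and MALAT1 at 110.2 FPKM.

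The authors' deposited table called 1365 genes, 1110 higher and 255 lower in shFBL. Each of these calls in the authors' deposited table had a q-value of at most 0.0499 and an absolute log2 fold change of at least 1. Of the 1365 genes 937 lay below the FPKM filter used here. Of the 428 tested, 427 were also called here, all 427 with the same direction. In the authors' deposited table FBL had a log2 fold change of -2.26 (q = 7.6e-218) and YBX1 one of 0.12 (q = 0.381). The log2 fold changes of the authors' deposited table and of the fit made here had the same sign for 99.3% of the tested genes.

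The authors' deposited table of KEGG gene sets held 304 sets, of which 2 had a positive and 145 a negative score at a q-value under 0.05. The 2 positive sets of the authors' deposited table were systemic lupus erythematosus (normalised score 2.27) and alcoholism (2.04), both of which include histone genes. By the deposited KEGG annotation, 32 of 48 tested genes of the first set are histone genes, of which 24 rose, and of its 16 other genes 0 rose and 8 fell. In the authors' deposited table the sets ribosome (1.58, q = 0.098), ribosome biogenesis (1.58, q = 0.0761) and steroid biosynthesis (1.55, q = 0.0841) had positive scores. Among the lowest scores of the authors' deposited table were those of DNA replication (-2.56), cell cycle (-2.40) and cellular senescence (-2.26). Repair sets of the authors' deposited table also had negative scores, with -2.02 for base excision repair, -1.89 for the Fanconi anaemia pathway, -1.79 for mismatch repair, -1.66 for homologous recombination and -1.63 for nucleotide excision repair. Negative scores were common, with 258 of the 304 sets of the authors' deposited table. Its prostate cancer (-2.27) and basal cell carcinoma (-2.21) sets lay below every repair set named. For base excision, mismatch, recombination and nucleotide excision repair the lists tested here did not pass, and neither did those of p53 targets and the spliceosome. The nucleotide excision list tested here had an upward median of 0.12. The gene sets and tests differ between the sources.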

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

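The GC and length correction, the restriction to nuclear protein-coding genes, the scaling on nuclear protein-coding genes and the omission of the libraries with haemoglobin transcripts were chosen after seeing the data. FBL fell past the threshold in every alternative run, with log2 changes from -2.25 to -2.06. YBX1 passed with quantile normalization (0.177), the scaling on nuclear protein-coding genes (0.211) and the GC and length correction (0.227), and the cause was not tested. The 4145 genes called became 2485 (1042 higher, 1443 lower) without a filter, where 34485 genes were tested, and 162 (115 and 47) with a fold change of at least 2. Leaving out the 2 shFBL libraries with haemoglobin transcripts, so that 1 shFBL library was assumed to vary like the shControl libraries, gave 1749 (809 and 940), of which 1611 were among the 4145. A filter at 5 FPKM, with 7177 genes tested, gave 937 higher and 1997 lower genes. The share of calls that were higher was 31.9% there, against 43.3% in the main fit. Higher genes were thus lost more than lower ones. The scaling on nuclear protein-coding genes, which by construction raised all values of the shFBL libraries relative to shControl, gave 3275 higher genes. Leaving out single libraries gave 2914 to 3630 genes, and between 1167 and 1801 higher ones. In every alternative the called genes shared with the 4145 kept their direction. The 16 lists called became 27 without a filter (the cause was not tested) and 0 by camera with an estimated correlation, where the lowest adjusted p was 0.285 and 2 lists had an unadjusted p under 0.05. Fry called 11, among them intestinal differentiation (adjusted p = 0.0199), which is not 1 of the 16. It did not call the ribosomal protein, ribosome biogenesis, integrated stress response, lysosome, Fanconi and oxidative phosphorylation lists. Single lists kept their direction wherever they passed, with 46 calls lost and 29 gained over all lists and alternatives. The authors' calls would number 6198 at a q-value under 0.05 alone. Of 198 named genes called, 143 kept call and direction in every alternative that tested them. HBA1, not called, had a log2 change of 0.98 that became -1.28 without the haemoglobin-bearing libraries, by construction. With the replicate number as a block 3707 genes and 14 lists were called, without the oxidative phosphorylation and lysosome lists, FBL changed by -2.20 and YBX1 by 0.12. Deviations of same-numbered libraries had correlations of 0.097, -0.068 and -0.079, so no shared effect of the number was seen. This cannot show whether same-numbered libraries were made together. Absolute depth is unknown, which leaves low genes without a counting error.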

Other observations

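The tests of RNAs without poly(A) tails on which FBL does not act (the third measure tried), of the replication list against the histone genes, and of single libraries for the ribosomal lists were chosen after the result was seen. Outside the histone list, the 10 largest rises among protein-coding genes, chosen after their values were seen, included 4 members of the NBPF family (NBPF19, NBPF20, NBPF26 and NBPF12), the sterol genes MSMO1 and HMGCS1, and the histone genes H2AC19 and H2AW. HMGCS1, which makes the precursor of mevalonate, rose from 6.18 ± 0.726 to 13.3 ± 0.985 FPKM. NBPF26 rose from 7.04 ± 1.17 to 16.4 ± 0.879 FPKM. NBPF genes are near-identical copies, so values of single members are uncertain. Long non-coding RNA genes as a class had 261 rises and 34 falls of 936, with a median log2 change of 0.25. NEAT1, which has a short polyadenylated form and was chosen after its values were seen, rose by 0.33 (adjusted p = 0.0401), against 3.58 for MALAT1.

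Splicing and protein folding genes went both ways. Of 40 spliceosome genes 14 fell and 8 rose (17 and 9 adjusted over the list alone, adjusted p = 0.39 for the list). SF3A2 fell from 50.6 ± 5.05 to 22.6 ± 1.33 FPKM, and SF3B4, SNRPA and SNRPB fell by log2 changes of -0.78, -0.66 and -0.48. Of 18 heat shock genes 7 fell and 2 rose (8 and 4 adjusted over the list alone, adjusted p = 0.134). HSPB1 fell from 182 ± 6.24 to 120 ± 1.93 FPKM and HSPH1 rose from 3.11 ± 0.328 to 5.87 ± 0.398 FPKM. Of 32 interferon-stimulated genes 8 fell and 1 rose (adjusted p = 0.116), led by IFI35 (-1.07) and OAS3 (-0.71). The vimentin gene VIM fell by -0.65, and the junction genes JUP and CLDN4 by -0.81 and -0.75, in lists that did not pass (adjusted p = 0.383 and 0.188). Housekeeping references, with 6 falls and 1 rise of 15 (8 and 1 adjusted over the list alone), stood at an adjusted p of 0.0542 and between 0.000586 and 0.108 over the alternatives with the preset correlation, and at 0.992 with an estimated one. They passed without a filter on low values (0.000586), after the GC and length correction (0.0316), with median-ratio scaling (0.0393), without shControl replicate 1 (0.037), shControl replicate 2 (0.0432) or shFBL replicate 2 (0.026), and without both libraries with haemoglobin transcripts (0.0272). In another split of the libraries they reached 0.0482. GAPDH, chosen after its values were seen, was among their falls (-0.29) and did not pass after the GC and length correction. Antigen presentation (0 rises and 5 falls of 14, adjusted p = 0.117), NRF2 targets (2 and 7 of 19, 0.314), glycolysis and hypoxia (6 and 8 of 31, 0.888), the proteasome (6 and 6 of 31, 0.867), MYC targets (2 and 2 of 25, 0.932) and the unfolded protein response (4 and 4 of 23, 0.993) did not pass either. Adjusted over the list alone these counts were the same but for 3 rises of NRF2 targets, 9 falls in glycolysis and 5 falls in the unfolded protein response. Without a filter on low values the spliceosome, heat shock, interferon, antigen presentation, junction, matrix, NRF2 and housekeeping lists passed. In intestinal differentiation the carbonic anhydrase CA2 and the transcription factor KLF4 fell, and CDX2 did not pass. The median, mean and direction of the test differed in sign for the proteasome (-0.025, 0.014, upward), apoptosis regulators (0.026, -0.041, downward), MYC targets (0.017, -0.021, upward), tRNA synthetases (0.032, -0.004, upward) and the box H/ACA proteins (-0.035, -0.007, upward).

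The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4145 genes and the highest other split 1, and 1 of the 10 splits called as many. For lists the real split called 16 and the highest other split 17, so 2 of the 10 called as many. In another split the ribosomal protein list reached an adjusted p of 9.5e-18, the oxidative phosphorylation list 2.13e-08 and the lysosome list 0.0273, each below its real value. Of the 16 lists called, 14 passed in at least 1 other split, with a lowest adjusted p of 3.19e-07 for the replication and mitosis lists and 3.2e-06 for the histone list, and 9 lists not called passed there too. Each other split leaves 2 libraries of 1 group on the same side, so it keeps part of the group difference.

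If the rise of RNAs without poly(A) tails came from more such RNA carried through poly(A) selection in the shFBL libraries, box H/ACA snoRNAs, which FBL does not bind, would rise too, and the median of the 20 tested was 0.591 (0.43 to 0.83), beside 0.546 for box C/D snoRNAs. The filter favours genes that rose, and the H/ACA median was 0.471 (0.018 to 0.651) over the 11 with at least 1 FPKM in 2 or 3 shControl libraries. It was 0.591 (0.417 to 0.907) over the 6 with it in all 3, and 0.052 over all 139. For box C/D snoRNAs these medians were 0.405 (0.014 to 0.632) over 29, 0.262 (-0.052 to 0.546) over 18 and 0.015 over all 149. How alike the 2 kinds were thus depended on the members taken. Mitochondrial tRNAs rose less evenly, with 12 rises among 22 and members from -0.431 to 1.924. Of 16 snoRNA host genes 11 rose and 1 fell, with a median of 0.329, and reads from host transcripts were not separated from those of snoRNAs. Carry-through stays a candidate explanation, and a difference in library preparation was not tested, since the labels give no batch. Loss of the direct action of FBL on ribosomal RNA and box C/D snoRNAs would not account for the whole rise, because 3 classes on which FBL does not act rose too. These were box H/ACA snoRNAs, replication-dependent histone genes, and RNA polymerase III transcripts with RNase P and MRP RNAs. The measure was chosen after their rise was seen, so it describes that rise and is no independent test. FPKM was summed over all members of each class without a filter. The gaps between the lowest shFBL and the highest shControl library were 0.791, 2.354 and 3.07 on the log2 scale, against ranges within a group of up to 0.482. These sums rest on the most abundant members, and the median over the 3 classes depended on the members taken, from 0.112 over all to 0.966 over those with at least 1 FPKM in all 3 shControl libraries, while later effects of the knockdown were not tested and stay open. If more cells in S phase caused the histone part, the replication list was predicted to rise, and its median was -0.482 with an interval below 0. The histone genes thus did not rise together with the replication genes. That list measures transcripts and not the share of cells in S phase, which was not measured, so this cause cannot be excluded.

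The fall of replication and mitosis genes stayed under both technical tests run. Dilution of mRNA by the RNAs that rose would bring the median near 0 when libraries are scaled on nuclear protein-coding genes, and it was -0.447 (-0.49 to -0.38), against -0.54 as deposited. A bias from GC content or length would leave a residual near 0, and the median residual was -0.561 (-0.61 to -0.49). A lower share of cycling cells after FBL knockdown under mitomycin C may therefore be proposed as a hypothesis, found and tested on the same libraries. Library preparation stays open here too, and cells without the drug or a measure of cell cycle phase were not analysed here.

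The upward shift of the ribosomal protein and ribosome biogenesis lists was smaller. GC content or length does not account for it, as the median residual was 0.182 (0.15 to 0.23) against 0.164 as deposited. Differences between single libraries within the groups cannot be told apart from a group effect. The lowest shFBL library median lay 0.05 above the highest shControl one, less than the widest range inside a group, 0.116.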
